A study of Mus musculus with 4 samples.

How the data were processed

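The authors deposited raw UMI counts per gene and cell for 4 libraries of mouse bone marrow cells: WT c-Kit+, KO c-Kit+, WT MLL-AF9 and KO MLL-AF9. According to the submitters' processing notes the reads were processed with Cell Ranger 7.1.0 against mm10. The gene annotation is not stated. All values are whole numbers with differing library sums, and the replicate number of each group is 1. Each file lists 56941 features, of which 51948 have an ID in GENCODE M21 (GRCm38), the source of the positions given, and 4993 do not. Symbols shared by 2 or more IDs numbered 147. Whether the barcodes are those that Cell Ranger called or a later selection is not stated.

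Cells were kept with 500 or more genes, 1000 or more UMIs and at most 10% of UMIs from mitochondrially encoded genes, and doublets called by Scrublet in scanpy 1.11.5 (run per library, expected doublet rate 0.08) were removed. The filter kept 12426 of 13480, 13209 of 14577, 12685 of 14167 and 11315 of 12762 barcodes, with 87366665, 95219464, 86535650 and 94179795 UMIs. Scrublet called between 3.64% and 4.03% of the cells that passed the other filters. Mitochondrial UMIs made up 0.747%, 0.693%, 1.03% and 0.862%, ribosomal protein genes 11.3%, 12.4%, 10.4% and 8.75%, haemoglobin genes 0.799%, 0.984%, 0.228% and 1.17%, and Malat1 0.528%, 0.531%, 0.983% and 1.20%, in the order above.

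UMIs were summed over the kept cells of a library and divided by the library's sum to give CPM. The log2 ratio of a gene used a pseudocount of 1 CPM. UMI sums have exact Poisson intervals, ratios have exact conditional binomial intervals and shares of cells have exact Clopper-Pearson intervals, all at 95%. With 1 library per group no test, p-value or count of changed genes is given. The comparisons were KO against WT in MLL-AF9 cells, KO against WT in c-Kit+ cells, MLL-AF9 against c-Kit+ in WT, and the difference of the KO effects.

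For each of 13 gene lists the median log2 ratio was taken over members with a mean of 5 CPM or more, and placed among 10000 random lists of the same size drawn from genes in the same of 20 bins of mean CPM. A list stands apart at a percentile of 2.5 or less or 97.5 or more. The lists were MLL-fusion and self-renewal, MYC targets, S phase, G2M, p53 and apoptosis, spliceosome, interferon, antigen presentation, oxidative phosphorylation, glycolysis, myeloid maturation, immediate early and heat shock, and ribosomal protein genes. All 517 members of the lists were found in the files.

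The genes named in the text follow a rule. Rbm5, Rbm6, Rbm10, Myc, Meis1, Hoxa9, Hoxa10, Mef2c, Myb, Kit, Cd34, Flt3, Mpo and Itgam were fixed for every comparison. They are given in the KO comparisons and in WT leukaemia against c-Kit+, but not for the difference of KO effects. The 12 highest and 12 lowest log2 ratios follow, among genes with a mean of 50 CPM or more whose composition-matched log2 ratio has the same sign and a size of 0.5 or more. For the other comparisons the 10 highest and 10 lowest are named without the composition rule. Mitochondrially encoded genes, Xist, Tsix, Y-linked genes, haemoglobins, immunoglobulin and T cell receptor segments and gene models named by a number were left out of the ranking. From each list up to 3 members with the largest ratios may be named. In leukaemia the composition rule rested on shared clusters that held few cells; over the nearest WT clusters, an added version, it named the same genes.

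Each pair of libraries was clustered jointly without integration on 2000 variable genes, leaving out the genes of every list except myeloid maturation and mitochondrially encoded, ribosomal, Xist and Y-linked genes. Clustering used 30 principal components, 15 neighbours and Leiden resolution 0.6 (igraph 0.11.9, scikit-learn 1.9.0). A cluster took the name of the best supported of 16 marker sets when at least 3 markers and at least 50% of the set were raised 1.5-fold at 50 CPM or more, and no other set had more markers among the 10 leading genes. Clusters without a marker of their set among these genes stayed unnamed when their median UMIs per cell in each library were below the library's median divided by 3. That naming rule was set after the clusters had been seen. Composition-matched sums average cluster CPMs with the same cluster weights in both libraries. They used clusters with at least 100 cells of each library or, as an added version, the WT library's own clusters with each KO cell placed by its nearest WT cells. Shares of cells with a UMI were also taken with each cell thinned to 2000 UMIs, shallower cells being left out.

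The groups, comparisons, gene lists, marker sets, naming rule for genes, filters and thresholds were fixed before the data were examined, as were the alternatives: 2 other cell filters, doublets kept, 2 other scalings, 2 other pseudocounts, 2 other level filters, equal weight per cell, thinned cells, 10 bins, composition-matched sums and, for clusters, other resolutions, list genes kept and classes of the nearest WT cells. Added after the data had been seen were matching over the nearest WT clusters, myeloid clusters alone, matched sums for the difference of KO effects, clustering of thinned cells and clustering without genes that differ across the whole library.

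The log2 ratios and intervals were tested on simulated Poisson counts at the depth of these libraries, for genes at 50 CPM or more in WT. All changed genes of 1.5, 2 and 4-fold were recovered within 0.2 on the log2 scale. The 95% ratio intervals held the true ratio for 95.2% of genes at leukaemia depth and 94.9% at c-Kit+ depth. Both outcomes largely follow from the depth and the Poisson draws, so they check the calculation only. The list percentile was tried on the real log2 ratios instead. Random lists of 40 genes stood apart in 5% of draws, a share that the random drawing itself sets. Such lists raised by 0.5 on the log2 scale stood apart in 99.5% and 100% of draws. Lists of genes that vary together were not covered. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, umap-learn 0.5.12 and matplotlib 3.10.9.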

Results

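Single-cell RNA was measured in 4 droplet libraries of mouse bone marrow, 1 library per group, so there were no replicates in any comparison. Cells labelled ckit+, the surface receptor by which blood stem and progenitor cells are usually enriched, came from a wild-type (WT) and from an Rbm5 knockout (KO) mouse. Cells labelled MLL-AF9, an acute myeloid leukaemia driven by a fusion of the MLL and AF9 genes, came from a WT and from a KO leukaemia. The files held 94266267 UMIs in 13480 barcodes of WT c-Kit+ cells and 101851873 UMIs in 14577 barcodes of KO c-Kit+ cells. They held 94122777 UMIs in 14167 barcodes of WT MLL-AF9 cells and 102884646 UMIs in 12762 barcodes of KO MLL-AF9 cells. After filtering, 12426, 13209, 12685 and 11315 cells were kept in that order, with medians of 5186, 5267, 5787 and 7301 UMIs per cell. Levels are given as CPM, the UMIs summed over the kept cells and scaled to a common library sum. Intervals are 95% intervals and cover counting error only, not the variation between mice or between leukaemias.

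Rbm5, the targeted gene, codes for an RNA-binding splicing factor (ENSMUSG00000032580, chromosome 9, 107740371 to 107770996 on the minus strand of GRCm38). It gave 6580 UMIs (75.3 CPM) in WT c-Kit+ cells, 8587 UMIs (90.2 CPM) in KO c-Kit+ cells, 13848 UMIs (160 CPM) in WT MLL-AF9 cells and 10908 UMIs (116 CPM) in KO MLL-AF9 cells. The KO over WT ratio was 0.724 (0.706 to 0.742) in leukaemia and 1.197 (1.16 to 1.24) in c-Kit+ cells. In leukaemia the log2 ratio of Rbm5 was -0.46, near the median of all genes of -0.38. With size factors from the median ratio over the 4 libraries its leukaemia ratio was 0.926 (0.903 to 0.949). The transcript was thus present in both libraries labelled KO and was higher, not lower, in the c-Kit+ one. The labels do not name the deleted part of the gene, and 3′ tags outside that part would remain after a deletion, so these counts do not check the labels. Groups are therefore named below as the libraries labelled KO and WT. The paralog Rbm6 was lower in the leukaemia library labelled KO (161 CPM in WT, 91.6 CPM in KO), as was Rbm10 (36.5 and 19.6 CPM). In c-Kit+ cells the KO over WT ratio was 0.952 (0.927 to 0.978) for Rbm6 and 0.980 (0.927 to 1.04) for Rbm10. Both c-Kit+ ratios changed direction in some settings, such as cells thinned to equal depth.

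The comparison of the leukaemia libraries addressed whether loss of Rbm5 changes the self-renewal programme that MLL fusions maintain, and expression linked to MYC. Immediate early genes, which respond within minutes to stimuli or stress, were the most different group: 19 of 21 measured members of the immediate early and heat shock list were higher in the library labelled KO. Klf2 was at 85.1 CPM in WT and 5933 CPM in KO, a ratio of 69.7 (68.1 to 71.4), and Fosb and Egr1 differed by 67.8-fold (64.3 to 71.4) and 60.7-fold (56.8 to 64.9). Genes of DNA replication were lower in the library labelled KO, with all 42 measured S phase genes lower, among them Wdr76, Hells and Ung, and 37 of them lower with median-ratio size factors. Of the genes fixed in advance, the cytokine receptors Flt3 (24.4 and 4.17 CPM in WT and KO) and Kit (61.6 and 28.4 CPM), the stem cell antigen Cd34 (16.7 and 4.56 CPM) and the transcription factor Myb (315 and 145 CPM) were lower. Marker sums went both ways: immature blast markers, which include these 4 genes, were at 2259 and 1484 CPM, and stem and multipotent progenitor markers at 1171 and 1461 CPM. Mecom, singled out after its values had been seen, made up most of the last sum (954 and 1213 CPM). Of the partners of the MLL-fusion programme, Meis1 (508 and 345 CPM) and Hoxa9 (174 and 105 CPM) were lower and Mef2c was higher (930 and 1168 CPM). These directions held in each alternative processing for the genes named with CPM other than Mecom, and each describes 1 leukaemia against 1 other.

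Differences in leukaemia were broad. The log2 ratios of KO over WT had an SD of 0.80 over 9901 genes at a mean of 5 CPM or more, against 0.15 over 9562 genes in the c-Kit+ pair. Their median was -0.38, or -0.05 with median-ratio size factors, so changes are read against it. In plain CPM Myc was at 25.9 in WT and 13.01 in KO (ratio 0.503, 0.469 to 0.540). With median-ratio size factors the log2 ratio was -0.61 for Myc. With them Flt3 had -1.99, Cd34 -1.37, Myb -0.77, Kit -0.75, Hoxa9 -0.38, Meis1 -0.21 and Hoxa10 -0.08. Mef2c had 0.67. Mpo (206 and 244 CPM) and Itgam (315 and 330 CPM), which mark granulocytic and myeloid cells, had 0.59 and 0.41. With the nearest WT clusters matched, the median of all genes was -0.26. Myc was then at -0.37, against -0.94 in plain CPM, so little of its difference was left over the nearest WT clusters. Over the clusters that both libraries share it was at -0.53, where the median of all genes was -0.30. Over the nearest WT clusters Cd34 moved from -1.68 to -0.70, Myb from -1.11 to -0.71, Kit from -1.09 to -0.77 and Flt3 from -2.30 to -1.71, while Hoxa9 (-0.72 to -0.66) and Meis1 (-0.56 to -0.65) moved less. Hoxa9, Meis1, Myb and Flt3 were left out when cells were placed, while Myc, Cd34 and Kit could enter. How far each gene moved may thus depend in part on the matching itself. Mpo was lower in KO over the clusters that both libraries share (-1.29), which hold few cells, but higher over the nearest WT clusters (1.17). Itgam was higher in KO over the shared clusters (0.23) and lower over the nearest WT clusters (-0.28).

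The 12 genes with the highest ratios were Fosl1, Klf2, Fosb, Cxcl2, Egr1, Dusp1, Atf3, Fos, Trib1, Jun, Nr4a1 and Tnfaip6, with log2 ratios from 6.70 for Fosl1 to 4.72 for Tnfaip6. Most of them are immediate early transcription factors and their early targets. Each was also lower in the WT leukaemia library than in both c-Kit+ libraries, as Fos shows with 37.4 CPM in WT leukaemia, 434 and 436 CPM in WT and KO c-Kit+ cells, and 1631 CPM in the leukaemia library labelled KO. The 12 genes with the lowest ratios were Pcdh7, Auts2, Adgrl4, Apba1, Pecam1, Pbx3, Tifab, Iftap, Clec2i, Pik3cd, Igf2bp3 and Cbx5, with log2 ratios from -3.45 for Pcdh7 to -1.75 for Cbx5. Pbx3, a binding partner of HOXA9 and MEIS1, was at 993 CPM in WT and 250 CPM in KO (ratio 0.251, 0.248 to 0.255). Pcdh7, which codes for a protocadherin, was at 354 and 31.4 CPM (ratio 0.0887, 0.0854 to 0.0921). All 24 kept their direction in every alternative.

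**Figure D1:**
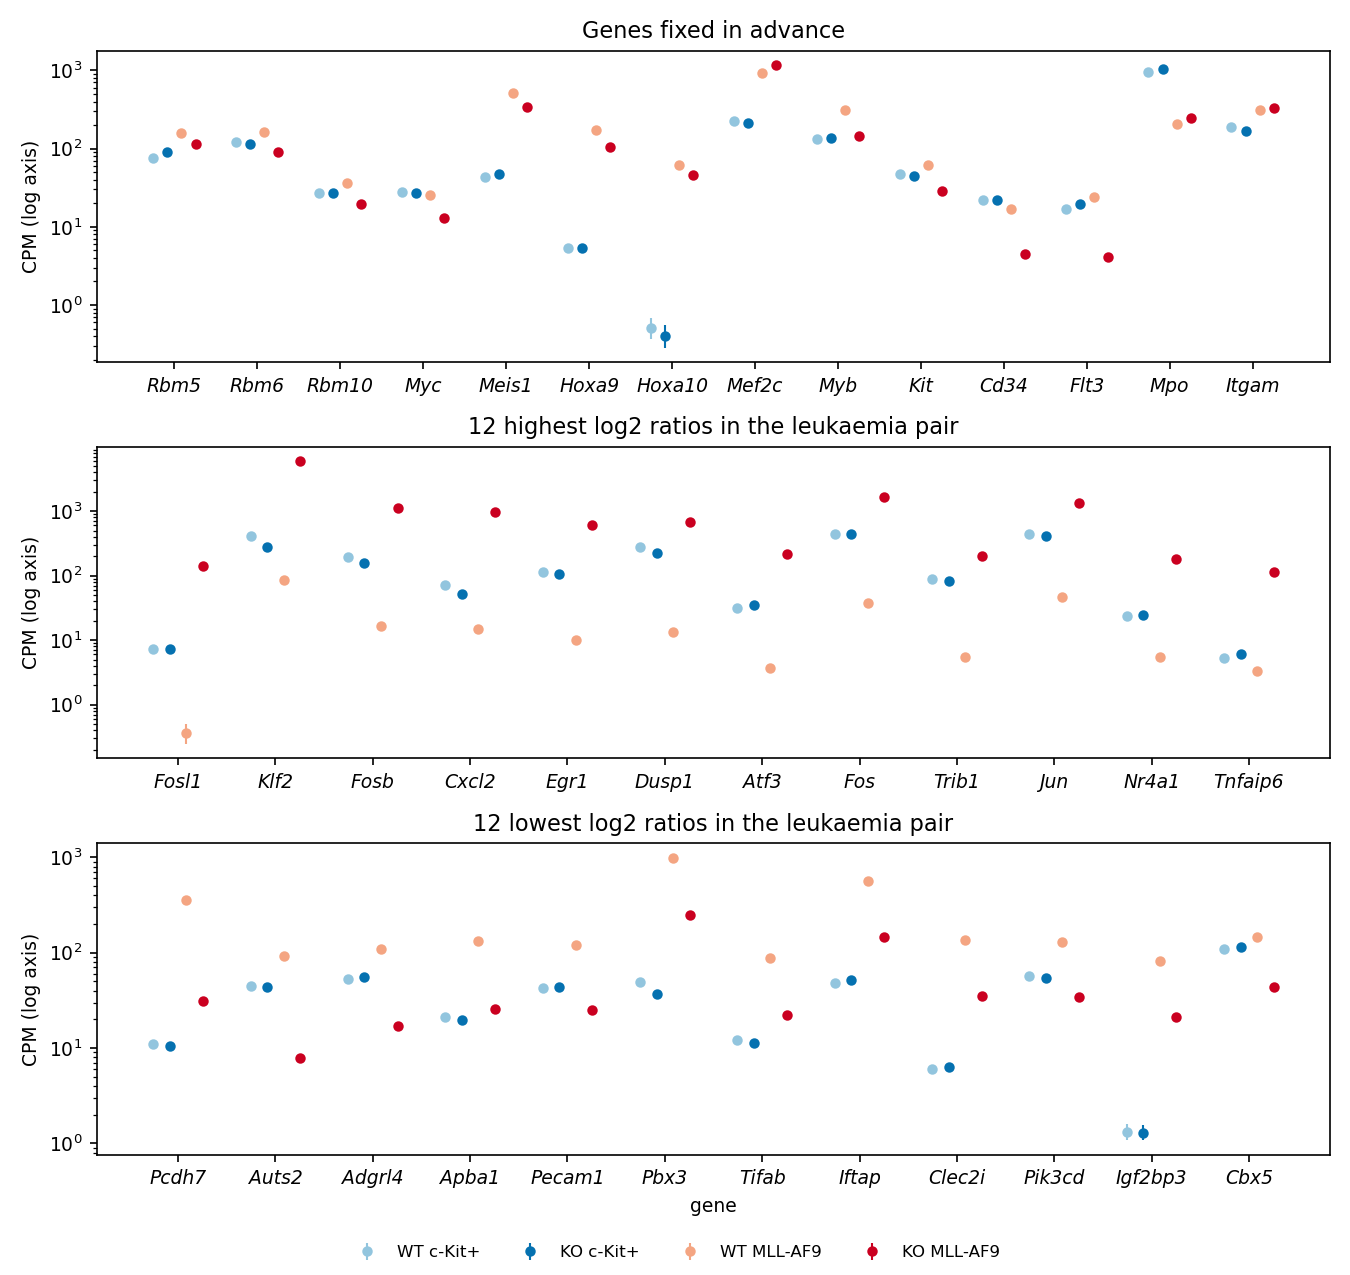
CPM on a log axis of the genes fixed in advance, of the 12 highest and of the 12 lowest log2 ratios of the leukaemia pair, in the 4 libraries; bars are exact 95% Poisson intervals of the UMI sums, often smaller than the points. In the middle panel the WT leukaemia points lie below the points of the other 3 libraries.

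The MLL-fusion and self-renewal list had a median log2 ratio of -0.49 in leukaemia, with 18 of 24 members lower in the library labelled KO, among them Flt3, Pbx3 and Cbx5, and 16 lower with median-ratio size factors. Its percentile among 10000 random lists matched on level was 2.96, which did not pass the limit of 2.5, and the median of those random lists was -0.25. It passed the limit in 6 of 15 alternatives: without the cell filter, at a mean of 25 CPM or more, with equal weight per cell, with thinned cells, over shared clusters and over the nearest WT clusters. The MYC target list had a median of -0.53 with 45 of 51 members lower, at a percentile of 7.95, and did not stand apart either. It passed on the low side at a mean of 25 CPM or more and in myeloid clusters alone, and on the high side over shared clusters. The sharpest differences inside it went both ways, with Dusp2 and Odc1 higher and Prmt3 lower. S phase genes had a median of -0.83 (percentile 0, no random list being as low) and G2M genes, which act at mitosis, had -0.60 (percentile 0.09, 48 of 51 lower, among them Ttk, G2e3 and Cbx5). With the nearest WT clusters matched the G2M median was -0.23 and the list no longer stood apart (percentile 50.6), while S phase genes still did. Without matching of clusters, the median of the random lists matched on level was -0.37 for S phase and -0.33 for G2M. Percentiles here are a description of these libraries, and a list is said to stand apart in the lowest or highest 2.5% of them.

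Myeloid maturation genes stood apart on the high side in leukaemia, with a median of 0.28 (percentile 99.98) and 24 of 36 members higher in the library labelled KO. The monocyte factor Klf4 was at 8.75 CPM in WT and 187 CPM in KO, the cytokine Il1b at 19.0 and 382 CPM and the receptor Cd14 at 27.1 and 413 CPM. The list still stood apart over shared clusters (0.41), but none of these was named as neutrophil or monocyte. It did not over the nearest WT clusters, where the median was -0.15 and on the other side of the random lists. Taken singly, it stood apart on the high side in 3 of 13 nearest WT clusters. Marker sums did not move together: in WT and KO, maturing neutrophil markers were at 75146 and 122609 CPM, monocyte markers at 2272 and 1471 CPM, neutrophil progenitor markers at 7276 and 6489 CPM and erythroid markers at 2420.4 and 12057 CPM. Glycolysis genes also stood apart on the high side (0.16, percentile 99.2, 11 of 17 higher, with Slc16a3 and Slc2a1). Antigen presentation genes were lower (-0.65, percentile 0.88, 14 of 15 lower), led by the class II genes H2-Eb1, H2-Aa and H2-Ab1, but not so as to stand apart over shared clusters (-0.47). Markers of cells that carry class II were lower as well: conventional dendritic 442 and 171 CPM in WT and KO, macrophage 145 and 42.8 CPM and B cell 66.3 and 17.5 CPM. The conventional dendritic markers include H2-Aa, H2-Ab1 and Cd74, which are also members of the list, so that sum is not separate evidence. B cell-like clusters held 0.788% of WT and 0.168% of KO cells. An unnamed cluster with H2-Aa, H2-Eb1, Cd74 and H2-Ab1 among its leading genes held 22.0% of WT and 0.415% of KO cells. Most clusters were of 1 library, so that share is not read as a difference in size. By the nearest WT cells a conventional dendritic-like class held 9.96% of WT and 7.11% of KO cells. Which cells account for the lower class II genes was not tested. Ribosomal protein genes had a median of -0.24 (percentile 0.65, 67 of 75 lower), but their median was positive with median-ratio size factors, and the call ended over shared clusters, without the level filter and with 10 bins and changed sides over the nearest WT clusters. The oxidative phosphorylation (-0.40, percentile 4.62), spliceosome (-0.37, 14.1), p53 and apoptosis (-0.37, 58.5) and interferon (-0.39, 65.3) lists did not stand apart. Within the p53 and apoptosis list Plk2, Cdkn1a and Bbc3 were higher in the library labelled KO, Cdkn1a at 10.6 CPM in WT and 99.2 CPM in KO, and the list's mean log2 ratio was 0.35, on the other side of 0 from its median.

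**Figure D2:**
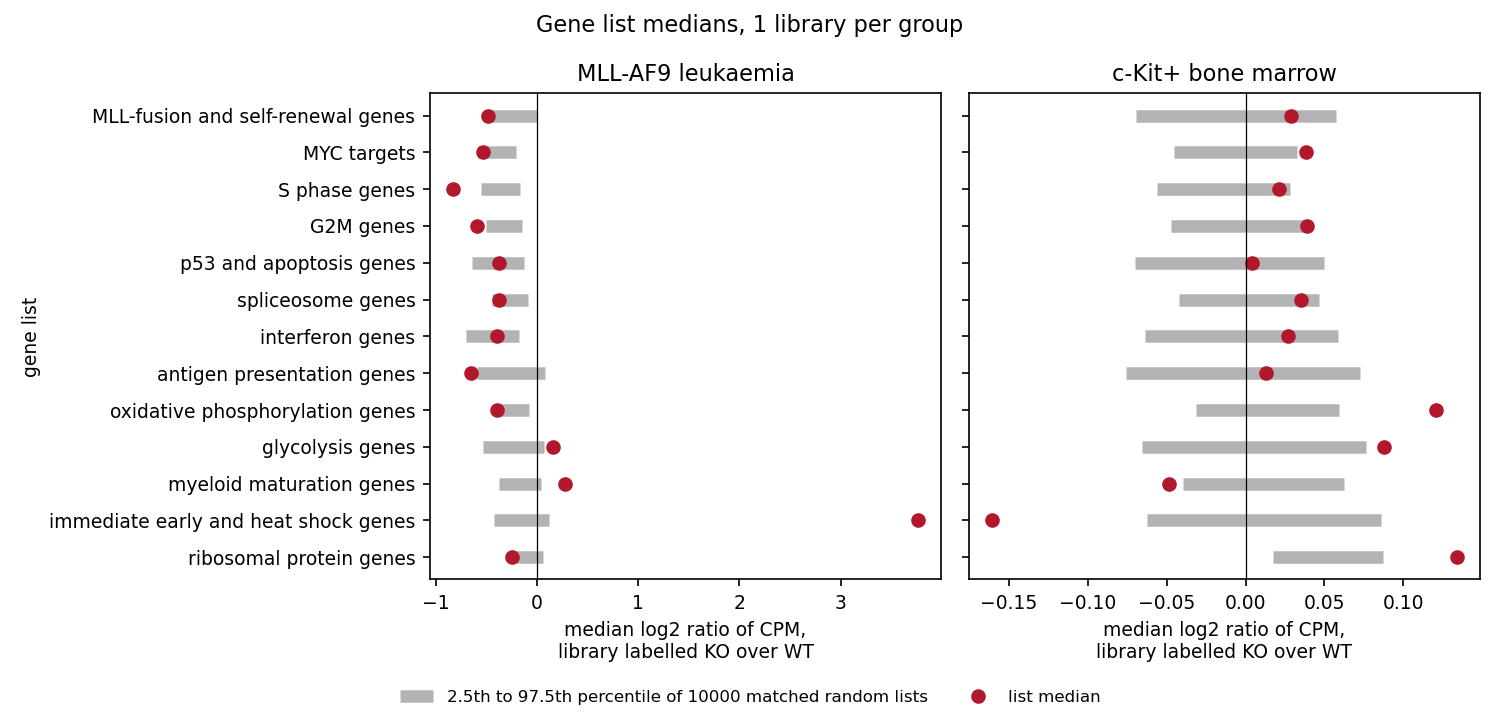
Median log2 ratio of CPM, library labelled KO over WT, of the 13 gene lists (points) and the range without the lowest and the highest 2.5% of 10000 matched random lists (grey bars), in leukaemia and in c-Kit+ cells; the horizontal scales of the panels differ. The immediate early and heat shock list lies at 3.76 in leukaemia and at -0.16 in c-Kit+ cells.

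Cells of the leukaemia libraries were grouped mostly by library. When the pair was clustered together without integration, 12 of 18 clusters were 90% or more of 1 library, and they held 92.6% of the WT cells and 93.8% of the KO cells. In the c-Kit+ pair none of 20 clusters was so. Cells are counted here by whole clusters, so no interval is given. A naming rule for clusters was set after the clusters had been seen, and it left 64.7% of WT and 12.4% of KO leukaemia cells without a class. Shares of leukaemia classes are therefore not read as differences in size: maturing neutrophil-like clusters held 18.0% of WT and 49.8% of KO cells, but they were separate clusters in each library and the shares moved with the settings. Clusters that both libraries share, with at least 100 cells of each, held 5.33% of WT and 5.72% of KO cells. They were the erythroid-like cluster, the T or NK cell-like cluster and an unnamed cluster with a median of 1709 UMIs per cell. Matching over them thus covers no cluster named as neutrophil or monocyte.

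Within cell states the lists were compared over the 13 clusters of the WT leukaemia library with at least 100 cells of each library, each KO cell being placed with its nearest WT cells; these clusters held 97.8% of WT and 99.5% of KO cells. The immediate early and heat shock list stood apart on the high side in all 13, with medians from 2.87 to 5.19. The MLL-fusion and self-renewal list stood apart on the low side in 8 of 13 and on the high side in 1, with medians from -0.995 to 0.26. The lowest of these was in the erythroid-like cluster, so the lower level was not limited to leukaemia-like cells, and whether the whole library or free RNA accounts for part of it was not tested. S phase genes stood apart on the low side in 5 and on the high side in none. MYC targets stood apart on the low side in 1 and on the high side in 4, and G2M genes in 3 and 2. This placing of cells was chosen after the data had been seen, while in the 3 shared clusters the immediate early list stood apart in 3 and the MLL-fusion list in 2, of which 1 was erythroid-like (-1.05). There G2M genes stood apart on the low side in 2, S phase genes on the low side in 1 and MYC targets on the high side in 2. In the 17 shared clusters of the c-Kit+ pair the MLL-fusion list stood apart on the low side in 1 and the immediate early list in 9.

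**Figure D3:**
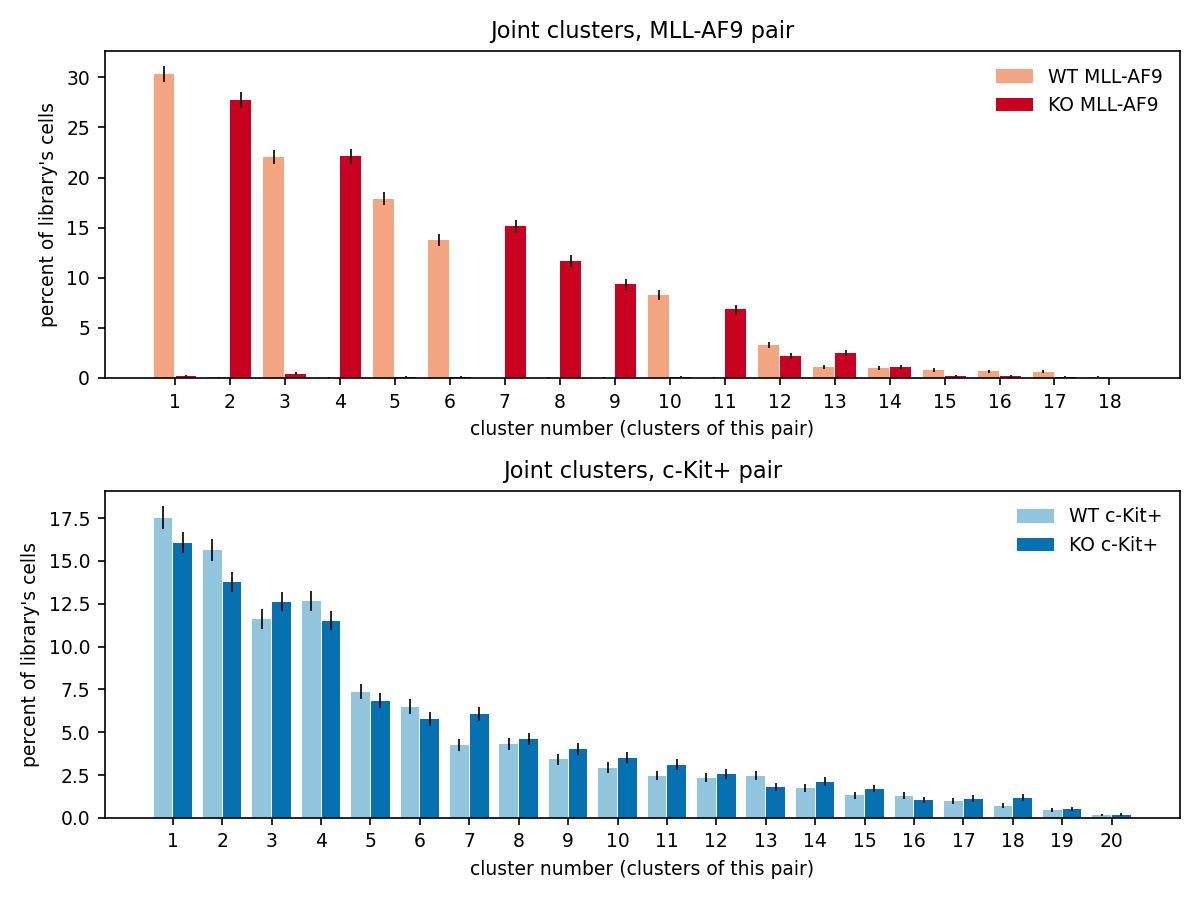
Percent of each library's kept cells in each cluster of the leukaemia pair and of the c-Kit+ pair, with exact 95% Clopper-Pearson intervals as error bars. The bars of WT and KO lie side by side in the c-Kit+ pair, while in the leukaemia pair 12 of 18 clusters belong almost wholly to 1 library.

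Fewer leukaemia cells of the library labelled KO had a UMI of the fusion programme's Meis1 and Hoxa9 at equal depth. Thinning does not remove the broad shift, as the median log2 ratio of all genes was -0.42 with thinned cells. Lower shares are therefore not particular to these genes. Mef2c and Mecom, which had higher CPM in KO, were not examined in this way. With each cell thinned to 2000 UMIs, Meis1 was seen in 58.4% (57.5 to 59.3) of WT and 43.3% (42.4 to 44.3) of KO cells outside the T or NK cell-like cluster, and in 10.7% and 1.89% of cells inside it, where the gene should be absent. Hoxa9 was seen in 27.0% (26.2 to 27.9) of WT and 18.4% (17.6 to 19.1) of KO cells, with 4.85% and 1.89% in the T or NK cell-like cluster, and Kit in 9.41% (8.88 to 9.96) and 4.48% (4.09 to 4.89), with 1.94% and 0.943%. Mpo was seen in 8.45% (7.95 to 8.98) of WT and 8.28% (7.76 to 8.82) of KO cells, with 3.88% and 0.943% in the T or NK cell-like cluster (4 and 1 cells), so these shares do not show that its expression was equal. Thinning left out 1166 WT and 495 KO cells outside the T or NK cell-like cluster and 22 and 14 inside it, and the unthinned shares for Meis1 were 84.3% of WT and 74.7% of KO cells at median depths of 5814.5 and 7320.0 UMIs, with 12.8% and 5.83% of T or NK cell-like cells at median depths of 4029 and 5275.5 UMIs. In c-Kit+ cells Kit was seen in 6.01% of WT and 6.40% of KO cells at equal depth, and in 9.16% (4.82 to 15.5) and 13.7% (8.77 to 19.95) of T or NK cell-like cells, so that this cluster gives no background for Kit here. Thinning left out 1391 WT and 1705 KO cells outside that cluster and 33 and 64 inside it.

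The comparison of the c-Kit+ libraries asked how the KO differs from WT in normal cells. Differences were small, with a median size of the log2 ratio of 0.08 against 0.53 in leukaemia. The genes named by rank included 3 that were higher in the library labelled KO, Ifitm1 at 58.3 and 91.1 CPM in WT and KO (ratio 1.56, 1.51 to 1.62), Ifitm6 at 851 and 1191 CPM (1.40, 1.39 to 1.41) and Ifitm2 at 340 and 471 CPM (1.39, 1.37 to 1.41). Mir6236 was higher as well, and Tmcc1 (285 and 180 CPM, ratio 0.629, 0.617 to 0.642) and Hcst (128 and 83.3 CPM, ratio 0.649, 0.631 to 0.668) were lower. These 6 were the only genes that met the naming rule. None of Myc, Hoxa9, Hoxa10, Myb or Cd34 had a KO over WT ratio whose interval left out 1, while the intervals of Meis1 (1.08, 1.04 to 1.13), Flt3 (1.15, 1.07 to 1.23) and Mpo (1.09, 1.08 to 1.10) lay above 1 and those of Kit (0.951, 0.911 to 0.993), Mef2c (0.942, 0.924 to 0.961) and Itgam (0.892, 0.872 to 0.911) below. Meis1 and Mpo were lower in KO when clusters were matched, and Kit was higher when cells were thinned.

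Of the gene lists in c-Kit+ cells, oxidative phosphorylation (0.12, percentile 100, 46 of 52 higher) and ribosomal protein genes (0.13, percentile 100, 72 of 75 higher) stood apart on the high side. MYC targets (0.04, percentile 98.7), G2M (0.04, 97.8) and glycolysis genes (0.09, 98.9) did so by small amounts. MYC targets no longer stood apart with the stricter cell filter or over shared or nearest WT clusters, nor G2M genes with that filter or in myeloid clusters alone. Glycolysis genes no longer did so with thinning, equal weight per cell, a pseudocount of 10 CPM or at a mean of 25 CPM or more. Immediate early and heat shock genes were lower in the library labelled KO (-0.16, percentile 0, 16 of 19 lower, with Klf2 at 415 and 274 CPM), the opposite side from leukaemia, and myeloid maturation genes were lower too (-0.05, percentile 0.97, with Lyz2 at 3667 and 2676 CPM). The myeloid maturation list no longer stood apart over shared clusters (-0.02), over the nearest WT clusters (-0.02), without the level filter or without the cell filter, and maturing neutrophil-like cells were a smaller share of KO cells. The MLL-fusion (0.03, 86.0), S phase (0.02, 94.5), spliceosome (0.03, 90.8), interferon (0.03, 83.9), p53 and apoptosis (0.00, 66.9) and antigen presentation (0.01, 65.4) lists did not stand apart. Although the label is ckit+, maturing neutrophil-like cells made up 53.2% (52.3 to 54.1) of WT and 48.2% (47.3 to 49.0) of KO cells. Erythroid-like cells were 7.30% (6.85 to 7.77) and 9.79% (9.29 to 10.3), neutrophil progenitor-like cells 11.6% (11.1 to 12.2) and 12.6% (12.1 to 13.2), and basophil or mast-like cells 2.45% (2.19 to 2.74) and 1.80% (1.58 to 2.04). Unnamed clusters held 6.11% and 7.23%.

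WT leukaemia against WT c-Kit+ cells placed the leukaemia beside normal marrow cells. The MLL-fusion and self-renewal list was far higher in leukaemia, with a median log2 ratio of 1.86 (percentile 100) and 20 of 24 members higher. Hoxa9 was at 5.32 CPM in c-Kit+ and 174 CPM in leukaemia cells (ratio 32.7, 29.8 to 35.9), Hoxa10 at 0.504 and 62.1 CPM (123, 91.8 to 170.01), Meis1 at 43.7 and 508 CPM (11.6, 11.2 to 12.01) and Mecom at 20.8 and 954 CPM (46.0, 43.9 to 48.2). The other genes with the highest ratios were Cstdc5, Hpgd, Stfa1, Stfa2, Sgip1, Cstdc4, Penk, Dynlt5 and Epha7, 4 of which belong to the stefin cluster of cysteine protease inhibitors. The lowest were Prss34, Rgs1, Car1, Jchain, Slc25a21, Ccl4, Mcpt8, St6galnac3, Dusp1 and Ebf1, which include the basophil proteases Prss34 (325 and 0.0116 CPM) and Mcpt8 and the B cell genes Jchain and Ebf1. Of the other genes fixed in advance, Mef2c (log2 ratio 2.03), Myb (1.24), Rbm5 (1.08), Itgam (0.75), Flt3 (0.50), Rbm6 (0.42), Rbm10 (0.41) and Kit (0.39) were higher in leukaemia. Mpo (-2.20), Cd34 (-0.38) and Myc (-0.10) were lower, but Cd34 and Myc changed direction with thinned cells. MYC targets (-0.47), G2M (-0.29), S phase (-0.06), oxidative phosphorylation (-0.36), spliceosome (0.00), ribosomal protein (-0.08) and immediate early and heat shock genes (-2.34) stood apart on the low side, and interferon (0.92) and glycolysis genes (0.69) on the high side. The spliceosome, ribosomal protein and S phase medians lay near 0 and changed sign in some settings. The low immediate early and heat shock median may also reflect how the WT leukaemia library was handled, which was not tested. The p53 and apoptosis (0.50), antigen presentation (0.64) and myeloid maturation (0.51) lists did not stand apart. The median of all genes was 0.27, and the libraries carry different labels (ckit+ and MLL-AF9) and held cells of different sex. They also held different cell populations, with 53.2% of WT c-Kit+ cells being maturing neutrophil-like. At equal depth Hoxa9 was seen in 0.681% of WT c-Kit+ cells outside the T or NK cell-like cluster. Ratios of genes of immature cells may thus owe part of their size to cell make-up, which was not tested.

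The difference of the KO effects, leukaemia minus c-Kit+, asked whether the KO difference is the same in both. Across 8955 genes the log2 ratios of the pairs had a Pearson correlation of -0.072 and a Spearman correlation of -0.061; genes are not independent replicates. The genes with the highest difference were Klf2, Cxcl2, Fosb, Dusp1, Egr1, Fos, Atf3, Trib1, Jun and Junb, and those with the lowest were Pcdh7, Adgrl4, Inpp4b, Ebf1, Angpt1, Pecam1, Cstdc5, H2-Eb1, Iftap and H2-Ab1. The largest difference was 6.70 for Klf2, and the lowest was -3.36 for Pcdh7. The MLL-fusion (-0.60, percentile 0.875), MYC target (-0.55, 1.91), S phase (-0.89, 0), G2M (-0.62, 0.01), antigen presentation (-0.75, 0.22), oxidative phosphorylation (-0.52, 0.04) and ribosomal protein lists (-0.37, 0.05) stood apart on the low side. Myeloid maturation (0.36, 100) and immediate early and heat shock genes (3.99, 100) did so on the high side, and glycolysis (0.04, 97.2), p53 and apoptosis (-0.33, 73.4), spliceosome (-0.39, 12.2) and interferon genes (-0.48, 42.7) did not stand apart. The mean lay on the other side of 0 from the median for the glycolysis and the p53 and apoptosis lists here, for the MLL-fusion list in c-Kit+ cells and for spliceosome genes in WT leukaemia against c-Kit+ cells. Some of these calls did not hold with cell states matched. MYC targets changed sides over shared (0.05) and over the nearest WT clusters (-0.15), where ribosomal protein genes (0.07) did so too and the MLL-fusion, G2M and myeloid maturation lists no longer stood apart. Over shared clusters the antigen presentation, oxidative phosphorylation and ribosomal protein lists no longer stood apart. With 1 library per group these differences were not tested.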

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

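Of the tests below, those of depth and of genes that differ across the whole library were written before their results were seen, and all the others only after.

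In c-Kit+ cells and in leukaemia 4 gene lists stood apart on opposite sides when the library labelled KO was compared with WT, and the differences between the tissues were not tested. The median over a list's genes of the difference of their log2 ratios, leukaemia minus c-Kit+, was 3.99 for immediate early and heat shock genes, 0.36 for myeloid maturation genes, -0.62 for G2M genes and -0.37 for ribosomal protein genes. Outside the comparisons, Y-linked genes gave 201 CPM in WT and 201 CPM in KO c-Kit+ cells but under 1 CPM in both leukaemia libraries, and Xist gave 1449 CPM in WT and 726 CPM in KO leukaemia cells but under 1 CPM in both c-Kit+ libraries. The c-Kit+ libraries thus held male and the leukaemia libraries female cells, so leukaemia against c-Kit+ also compares sexes, while each KO and WT pair does not.

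The higher level of immediate early and heat shock genes in the leukaemia library labelled KO was not limited to leukaemia-like clusters. The list's median log2 ratio was 4.12 in the T or NK cell-like cluster and 2.88 in the erythroid-like cluster, which is what a difference of the whole library, such as the handling of the cells, would give. Free RNA is argued against in the T or NK cell-like cluster, since the list's share of the library's level there was 10.2 times that of neutrophil markers. In the erythroid-like cluster the gap was smaller, with shares of 0.356 for the list and 0.120 for neutrophil markers. A rise caused by the KO genotype in both tissues is argued against by the c-Kit+ median of -0.16. This holds only if the KO label of the c-Kit+ library is right, which the Rbm5 counts do not check. An effect of the genotype in leukaemia alone, reaching the T or NK cell-like and erythroid-like cells too, stays open beside handling. With 1 library per group no value decides between them. Which leukaemia library departs is not settled either. The list was also lower in WT leukaemia than in WT c-Kit+ cells (median log2 ratio -2.34, 19 of 21 members lower). Free RNA was examined only in the leukaemia library labelled KO.

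Most leukaemia cells lay in clusters of 1 library. Depth per cell is argued against, since with every cell thinned to 2000 UMIs such clusters still held 92.4% of the WT cells and more of the KO cells. Genes that differ across the whole library are argued against as the whole cause, since leaving out 701 of them gave 90.8% for WT cells. A difference between individual leukaemias, an effect of the genotype and smaller differences of handling stay open and were not tested.

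Cell cycle genes were lower in the leukaemia library labelled KO. For S phase genes the list's percentile stayed at 0.19 with nearest WT clusters matched, which argues against different shares of these clusters as the whole cause. S phase and G2M genes were left out when cells were placed, so the share of cycling cells inside a cluster can still differ. A different make-up of cell cycle states is therefore not argued against. For G2M genes the percentile was 50.6 after the same matching, and the median moved from -0.60 to -0.23, so that a different make-up may account for their lower level. Within the 3 clusters that both libraries share, however, the G2M list stood apart on the low side in 2. Whether the make-up differs by genotype or between individual leukaemias was not tested.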

How the results depend on the processing

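Matching over the nearest WT clusters, myeloid clusters alone, matched sums for the difference of KO effects, clustering of thinned cells and clustering without genes that differ library-wide were chosen only after the results had been seen. The side of a list is its side of the median of its matched random lists, and for each change below the cause was not tested unless stated.

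Of the list medians under the alternatives, 177 of 195 in the leukaemia comparison and 171 of 195 in the c-Kit+ comparison kept their call. So did 157 of 169 for WT leukaemia against c-Kit+ and 173 of 195 for the difference of KO effects. Changes of side by lists that stood apart in neither setting were not counted as changes. Immediate early and heat shock genes kept their side and their call in every alternative of every comparison.

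Rbm5 kept its direction in both pairs. Its leukaemia ratio moved to 0.926 with median-ratio size factors and to 0.651 with thinned cells. Its leukaemia log2 ratio was -1.14 over shared clusters, which hold few cells, and -0.48 over the nearest WT clusters, against -0.46.

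In leukaemia the MLL-fusion list, at -0.49 just short of the limit, passed it on the low side with no cell filter (-0.50), at a mean of 25 CPM or more (-0.56), with equal weight per cell (-0.58), with thinned cells (-0.54), over shared clusters (-0.58) and over the nearest WT clusters (-0.48). MYC targets passed it at 25 CPM or more (-0.57) and in myeloid clusters alone (-0.62), but took the other side over shared clusters (0.068), where few cells remain. Over the nearest WT clusters G2M (-0.23), interferon (-0.53), myeloid maturation (-0.15) and ribosomal protein genes (0.14) changed sides. Antigen presentation genes no longer stood apart over shared clusters (-0.47), nor did ribosomal protein genes there (-0.11), without the level filter (-0.23) or with 10 bins (-0.24). Oxidative phosphorylation genes did so with the stricter cell filter (-0.42).

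In c-Kit+ cells thinning let the MLL-fusion (0.10), S phase (0.10) and spliceosome lists (0.077) stand apart and glycolysis (0.058) no longer. Equal weight per cell did so for S phase (0.11), spliceosome (0.084) and interferon genes (0.14), and no longer for glycolysis (0.083). The stricter cell filter ended the calls of MYC targets (0.0264) and G2M genes (0.0267). Over shared clusters MYC targets (-0.0040) and myeloid maturation genes (-0.0184) no longer stood apart and interferon genes did (0.075); over the nearest WT clusters the same held, at 0.011, -0.0186 and 0.12. In myeloid clusters alone G2M genes (0.049) lost the call and spliceosome (0.10) and antigen presentation genes (0.15) gained it. Without the level filter interferon genes gained it (0.084) and myeloid maturation genes lost it (-0.0335), as they did without the cell filter (-0.0333). Glycolysis lost it with a pseudocount of 10 CPM (0.057) and at 25 CPM or more (0.052).

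For WT leukaemia against c-Kit+, myeloid clusters alone ended the calls of S phase (0.33), spliceosome (0.25), glycolysis (0.62) and ribosomal protein genes (0.18). Equal weight per cell ended those of spliceosome (0.18) and ribosomal protein genes (0.13), as did thinning (0.16 and 0.22). Antigen presentation and myeloid maturation genes gained the call with the stricter cell filter (0.88 and 0.64) and a pseudocount of 10 CPM (0.62 and 0.45).

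For the difference of KO effects the MLL-fusion list lost its call with a pseudocount of 10 CPM (-0.34), without the level filter (-0.37) and over the nearest WT clusters (-0.37). MYC targets lost it with equal weight per cell (-0.66) and thinned cells (-0.65), and changed sides over shared (0.051) and nearest WT clusters (-0.15). Over the nearest WT clusters G2M (-0.29) and myeloid maturation genes (-0.051) lost it, interferon genes gained it (-0.63) and ribosomal protein genes changed sides (0.068). Over shared clusters p53 and apoptosis genes gained it (0.027), and antigen presentation (-0.31), oxidative phosphorylation (-0.29) and ribosomal protein genes (-0.16) lost it. Antigen presentation genes also lost it with a pseudocount of 10 CPM (-0.41) and at 25 CPM or more (-0.45). Spliceosome genes gained it in myeloid clusters alone (-0.49). Glycolysis gained it with a pseudocount of 10 CPM (0.054), without the level filter (0.041), with thinned cells (0.12) and with the total without mitochondrial, ribosomal and haemoglobin genes (0.0094). The correlation of the KO effects changed sign to 0.032 over shared and 0.0617 over the nearest WT clusters.

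The share of maturing neutrophil-like cells moved, in WT and KO leukaemia, to 22.0% and 33.3% at resolution 0.3, 20.3% and 45.9% at resolution 1.2, 19.4% and 37.5% with doublets kept and 34.6% and 62.6% by the nearest WT cells, and in KO to 31.3% with list genes kept. In c-Kit+ cells it moved to 55.9% in WT and 51.1% in KO at resolution 0.3, and to 49.4% in KO by the nearest WT cells. The share of leukaemia cells in clusters of 1 library moved, in WT and KO, to 96.2% and 95.8% at resolution 0.3, 95.8% and 95.7% at resolution 1.2, 90.02% and 93.1% with doublets kept, 97.1% and 96.0% with list genes kept and 90.8% and 92.9% without library-wide genes, and to 94.7% in KO with thinned cells. It was 0 in each c-Kit+ library at every setting run for that pair. Clustering of thinned cells and clustering without library-wide genes were run for leukaemia only. Depth limits Hoxa10 in c-Kit+ cells, where the interval of its KO over WT ratio ran from 0.4996 to 1.25.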
